A study of Homo sapiens with 7 samples.

How the data were processed

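The series holds RNA sequencing of 7 human samples: primary hepatocytes, CdH, CdH_Hep, fetal hepatocytes and fibroblasts. Per the labels, total RNA was extracted, polyadenylated RNA was selected and strand-specific libraries were built with a TruSeq Stranded mRNA kit. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.5.2b, RSEM 1.2.31 and genome build hg19, without their settings. The notes do not say whether the counting used the strand, so reads of genes that overlap on opposite strands could have been shared, and RSEM splits reads between paralogs by estimate. Each deposited file lists 22318 genes by symbol with RefSeq transcripts. The deposited expected counts are RSEM's estimates of reads per gene, not scaled and not all whole. The deposited TPM are the same estimates over effective length, scaled by the authors to a sum of 1000000 per library, which was checked on the values. A gene annotation for hg19 was not used here, so no coordinates are given; a RefSeq table of another build was used to look up gene names and to keep genes that could describe a donor from being named.

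Samples were grouped by the record, as fixed before the data were examined. Because the file names differ from the recorded samples, an assignment of each file to the sample named in it was fixed at the same time as an alternative. The name heading each file's TPM column gave the same assignment as the file name. Both assignments went through the same steps. They gave 2 libraries each for hepatocyte and CdH and 1 each for the other 3 groups.

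Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group (16509 genes kept), TMM factors (0.52 to 1.56), a quasi-likelihood fit with group as the term over all 7 libraries and 2 residual degrees of freedom, and Benjamini-Hochberg adjustment with a threshold of 0.05. A group of 1 library was assumed to vary like the groups of 2. The contrasts were CdH against hepatocyte, CdH_Hep against CdH and CdH_Hep against hepatocyte. Levels are CPM on the TMM scale, as mean ± SD where a group has 2 libraries and as 1 value elsewhere; log2 CPM used a prior count of 2. Where every library of a group was at 0 counts, the fold is a bound computed with 3 counts per library in that group. Where a group had 1 to 3 counts, a ratio with its 95% counting interval is given. Intervals and limits of detection cover counting error only. Library totals ranged from 16875976 to 36916491 expected counts.

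The 16 gene lists, fixed before the data were examined, were mature hepatocyte secreted proteins, mature hepatocyte enzymes and transporters, liver transcription factors, hepatic progenitor and biliary markers, fetal liver markers, fibroblast and mesenchymal markers, proliferation, TGF-beta response, Wnt response, growth factor response, pluripotency markers, macrophage and leukocyte markers, endothelial markers, erythroid markers, stellate cell markers, and stress and acute phase genes. They were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and with an estimated one, adjusted over the lists. For CdH against hepatocyte, 1 list passed by the record and 6 by the header with the preset correlation, and 0 by either with the estimated one. For single libraries each list's median log2 difference was placed among 10000 random lists drawn from 20 bins of expression.

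Named genes were the 10 of largest fold in each direction among those that passed with a mean of at least 10 CPM in the higher group. Where fewer passed, genes of largest fold whose group ranges did not overlap filled the places. Besides these stand up to 4 members of highest level per list, members of small counts, and ALB, AFP, KRT19, SOX9, EPCAM, COL1A1 and MKI67. By the record the places were filled by genes that did not pass, which are all listed for CdH against hepatocyte and by example elsewhere. STAB1 by the record and APOA1, APOH, TTR, CYP2B6 and other members given as examples of a list were picked after their values were seen. Some genes that the rule names are not reported here.

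Alternatives were DESeq2 1.42.0, RLE size factors, no filter, only the libraries compared, limma on log2 TPM with a pseudocount of 1 or 0.1, a replicate block, leaving out each replicate of hepatocyte and CdH, and, chosen after seeing the data, library totals without TMM and some of these under the header assignment. Groups of 2 are too small for counts over other splits of the samples or for a rule on outliers. The fit was tested on simulated data with 200 changed genes. At the dispersion of the recorded groups, 0.748, it called 0 of 50 genes changed 64-fold in CdH against hepatocyte. At that of the header groups, 0.0934, it called 3, 41, 50 and 50 of 50 genes changed 2-fold, 4-fold, 16-fold and 64-fold, with 6 calls among 15561 unchanged genes. Apart from the changed genes, all simulated libraries had the same mean composition, and all genes the same dispersion. The simulation therefore cannot show how often unchanged genes are called where compositions differ, as between the libraries headed CdH and hepatocyte.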

Results

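Polyadenylated RNA was sequenced from 7 human samples in 5 groups: primary hepatocytes (2 libraries), CdH (2 libraries), CdH_Hep (1 library), fetal hepatocytes (1 library) and fibroblasts (1 library). CdH are progenitor cells that the study made from adult hepatocytes with a medium holding A83-01, an inhibitor of TGF-beta receptors, CHIR99021, a GSK3 inhibitor that activates Wnt signalling, and hepatocyte growth factor. CdH_Hep are hepatocyte-like cells derived from CdH, and the labels give no medium for that step. The questions set by the series are how CdH differ from primary hepatocytes, and how far CdH_Hep return toward hepatocytes. The labels do not say that the sequenced hepatocytes were the source of the CdH, so donor differences may be mixed into the comparisons. In a library's total of expected counts, 3 counts amounted to 0.081 to 0.178 counts per 1000000 (CPM). On the TMM scale, on which levels are given, 3 counts amounted to 0.0547 to 0.342 CPM. The highest values there, 0.342 and 0.255 CPM, were those of the libraries headed hepatocyte 1 and 2. That level is the limit of detection at this depth, for counting error only.

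The sample that GEO records for a file and the sample named inside it differed for 6 of the 7 libraries. The libraries recorded as hepatocyte 1 and 2 were headed CdH 1 and 2. The library recorded as fibroblast was headed CdH_Hep. The libraries recorded as CdH 1, CdH 2 and CdH_Hep were headed fibroblast, hepatocyte 1 and hepatocyte 2. The fetal hepatocyte library carried the same name in both places. Across the 16509 tested genes, which are not independent replicates, the log2 CPM of the pair recorded as CdH correlated at Pearson r = 0.54. The pair headed CdH correlated at 0.98 and the pair headed hepatocyte at 0.96. ALB, the main serum protein of hepatocytes, stood at 66 counts in the library headed fibroblast and at 1352057 counts in that headed hepatocyte 1. Those libraries are the pair recorded as CdH. COL1A1, a fibrillar collagen of fibroblasts, stood at 2482 and 3.08 CPM in the same pair. The pair recorded as CdH thus joins unlike libraries. Secreted liver proteins had median log2 CPM of 8.84 and 7.59 in the libraries recorded as hepatocyte, and 14.42 and 13.77 in those headed hepatocyte. These values argue against reading differences by the record as differences between the cells named. Every comparison is given first by the record and then by the header.

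**Figure D1:**
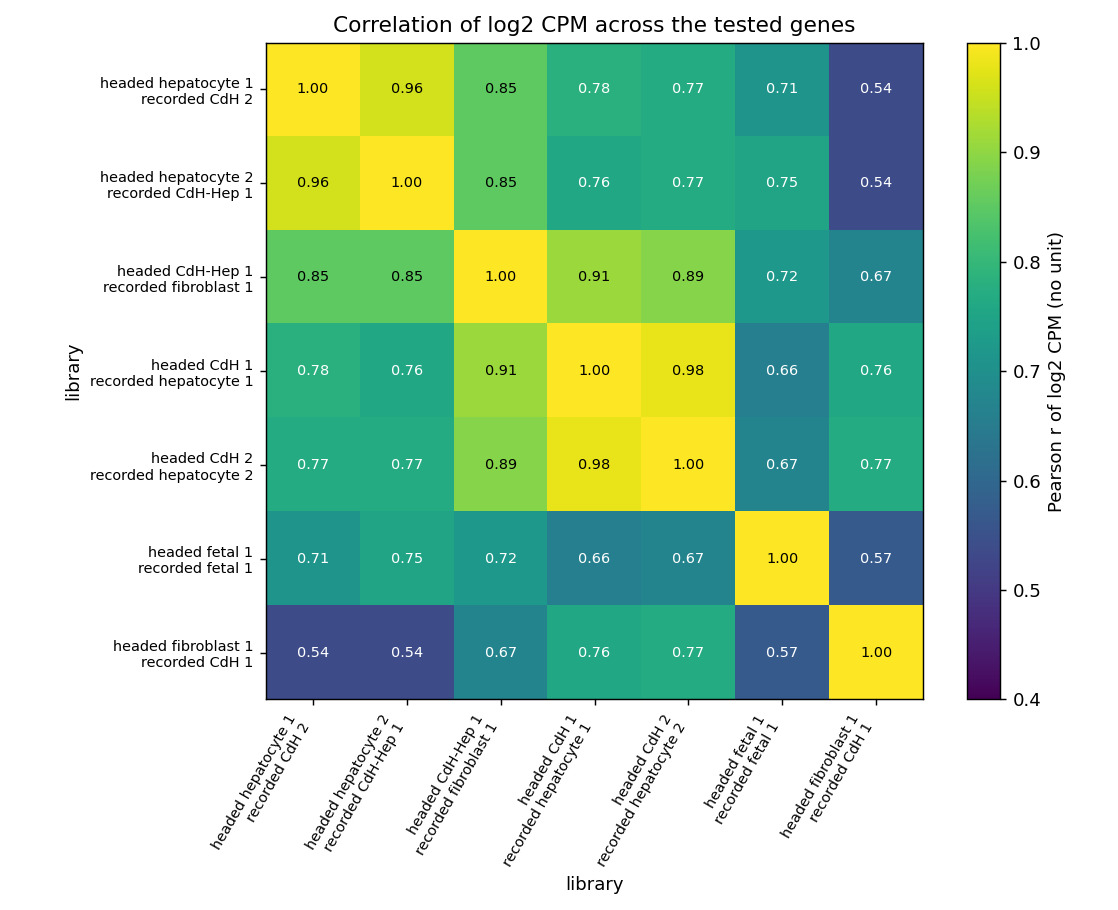
Pearson correlation of log2 CPM (color scale and printed values, no unit) between the 7 libraries, each axis listing a library by the name in its header and by its recorded sample. The pair headed CdH sits at 0.98 and the pair headed hepatocyte at 0.96, and the pair recorded as CdH at 0.54.

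By the record, no gene passed between CdH and hepatocyte, and the levels within the recorded CdH pair lay far apart. ALB stood at 77109 ± 109047 CPM in recorded CdH and at 8756 ± 2359 CPM in recorded hepatocyte (SD, n = 2 each). KRT19, a keratin of bile duct cells, stood at 153 ± 210 and 1699 ± 289 CPM, SOX9 at 1.35 ± 0.461 and 34.8 ± 8.68 CPM, and EPCAM at 0.518 ± 0.248 and 22.4 ± 8.44 CPM. AFP stood at 2.19 ± 2.87 and 5.51 ± 2.46 CPM, COL1A1 at 1242 ± 1753 and 13.0 ± 10.6 CPM, and MKI67, a proliferation marker, at 78.2 ± 110 and 69.2 ± 35.8 CPM. The genes with the largest folds upward whose ranges did not overlap were PCDH18, A1BG, ADAM33, FLT1, ENPP2, LY6K, IGF2, FAM65B, SLC8A1 and CD4. Of these, A1BG stood at 2020 ± 2851 CPM against 1.71 ± 0.633 CPM, and IGF2 at 1115 ± 1558 CPM against 1.69 ± 0.347 CPM. The largest downward were SLC6A19, SCEL, ANXA8L2, EPS8L3, ANXA8, TMEM233, HES2, ANKRD1, EHF and CTSE. ANKRD1 stood at 0.317 ± 0.0356 CPM against 470 ± 9.97 CPM. SCEL was at 0 counts in recorded CdH and at least 114-fold lower, and none of these 20 genes passed. ANXA8 and ANXA8L2 are near-identical copies whose reads are hard to tell apart.

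The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 16509 genes in this comparison, with 828 at an unadjusted p under 0.05 and 519 called by DESeq2. Of the 16 gene lists, 1 passed the set test camera: the hepatic progenitor and biliary markers were lower in recorded CdH, with a median log2 difference of -3.47 (adjusted p = 1.54e-09 with the preset correlation; adjusted p = 0.617 with an estimated correlation). None of its 15 members passed over all genes and 3 were lower when adjusted over the list alone. In that count over the list alone, the growth factor response and the stress and acute phase lists each had 1 lower member, and the other 13 lists had 0 in either direction. The median and the camera direction differed in sign for the liver transcription factors (median 0.96, test downward), proliferation (0.94), macrophage and leukocyte markers (1.38), stellate cell markers (0.88) and fetal liver markers (0.41). For the TGF-beta response the median was -0.68 and the mean 0.08. The labels do not say that replicates come from separate donors or cultures, so p-values of single genes measure the spread between these samples alone. Camera p-values with the preset correlation compare a list's genes with the other genes under an assumed correlation. Those p-values do not measure the spread between samples. Without either library recorded as CdH the count was 6596 (without the first) or 5935 (without the second).

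By the record, CdH_Hep and hepatocyte or CdH likewise gave no called gene. Recorded CdH_Hep held macrophage genes such as C1QA, a complement subunit, at 29.0 CPM, against 0 and 1.37 CPM in the libraries recorded as CdH. It held the endothelial scavenger receptor STAB1 at 34.9 CPM, against 0.0182 and 0.912 CPM. CRP, an acute phase protein of the liver, stood at 19296 CPM in recorded CdH_Hep and at 1.68 and 0.368 CPM in recorded hepatocyte. CPA4, a carboxypeptidase, stood at 0 CPM and at 945 and 630 CPM in the same libraries. For CdH_Hep against CdH the edgeR count was 0, with 217 genes at an unadjusted p under 0.05 and 141 called by DESeq2. For CdH_Hep against hepatocyte it was 0, with 744 unadjusted and 458 by DESeq2. Without CdH replicate 2 the first count was 8700, without CdH replicate 1 it was 6, and without these libraries the second count was 6997 and 7156. With the libraries compared alone in the fit, the second count was 7245.

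Among the gene lists, endothelial markers were the strongest upward call for recorded CdH_Hep against CdH, with a median log2 difference of 4.57 (camera, adjusted p = 4.29e-10 with the preset correlation; adjusted p = 0.696 with an estimated correlation). Macrophage and leukocyte markers had a median of 3.05 (adjusted p = 1.16e-05; adjusted p = 0.696 with an estimated correlation). Downward calls were fibroblast and mesenchymal markers, with a median of -7.45 (adjusted p = 0.00499; adjusted p = 0.708 with an estimated correlation), and proliferation, with -6.31 (adjusted p = 0.00406; adjusted p = 0.708 with an estimated correlation). Enzymes and transporters (median 0.08, adjusted p = 0.00499), stress and acute phase genes (0.87, 0.00737), secreted proteins (0.44, 0.00849) and liver transcription factors (0.65, 0.0127) were called upward, each with adjusted p = 0.708 with an estimated correlation. So were stellate cell markers (0.99, adjusted p = 0.00696; adjusted p = 0.696 with an estimated correlation).

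Against recorded hepatocyte, endothelial markers had a median of 3.95 (adjusted p = 3.01e-07; adjusted p = 0.654 with an estimated correlation). Hepatic progenitor and biliary markers had a median of -5.38 there (adjusted p = 5.65e-06; adjusted p = 0.654 with an estimated correlation), and macrophage and leukocyte markers of 4.41 (adjusted p = 0.00327; adjusted p = 0.654 with an estimated correlation). Enzymes and transporters (median 5.76, adjusted p = 0.00327), proliferation (-5.31, 0.00498), stress and acute phase genes (3.48, 0.0206) and secreted proteins (5.69, 0.0275) were called too, each with adjusted p = 0.798 with an estimated correlation. The median and the mean or the test also differed in sign for the Wnt response (median 0.45, mean -1.15), fetal liver markers (0.84 and -0.07), erythroid markers (-0.07 and 0.58) and pluripotency markers (median -2.06, test upward) in CdH_Hep against CdH. No list had a member passing over all genes for CdH_Hep against CdH or hepatocyte. Adjusted over the list alone, 1 endothelial member was higher in each, and against hepatocyte 3 progenitor members, 1 growth factor member and 1 stress member were lower.

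Assigned by header, an alternative fixed before the data were examined, the same fit called 6702, 1244 and 2778 genes in the 3 comparisons, and group names from here on are those in the headers. Genes of bile duct and progenitor cells were far higher in CdH than in hepatocyte, and secreted liver proteins and metabolic enzymes far lower. KRT19 rose 447-fold, from 3.81 ± 0.577 to 1699 ± 289 CPM, and KRT7, the other biliary keratin, rose 292-fold, to 1425 ± 123 CPM. ALB fell from 115962 ± 54101 to 8756 ± 2359 CPM, 13.2-fold, and HP, the haemoglobin-binding protein haptoglobin, fell 308-fold to 465 ± 504 CPM. The cell cycle gene MKI67 rose 272-fold, from 0.285 ± 0.403 to 69.2 ± 35.8 CPM. It was near the limit of detection in hepatocyte, at 5 and 0 counts, so the size of that fold is uncertain. AFP, a fetal liver protein, stood at 5.51 ± 2.46 CPM in CdH and 2.66 ± 2.20 CPM in hepatocyte and did not pass.

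The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 6702 of 16509 genes, 3767 higher and 2935 lower in CdH. DESeq2 called 6691, of which 6136 were shared, with 3313 higher and 3378 lower. Scaled by library totals instead of TMM, the median gene moved from 0.20 to 1.67 (log2), and 90.0% of 10877 called genes were higher. All folds are therefore relative to the TMM scale, on which few abundant secreted transcripts weigh little.

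The 10 genes of largest fold upward were CPA4, STC2, HES2, CXCL5, SERPINB2, TOP2A, ANLN, EREG, SLC35F3 and C6orf174. CPA4 was at 0 counts in both hepatocyte libraries and at 787 ± 223 CPM in CdH, at least 2636-fold higher. The stanniocalcin gene STC2 was at least 336-fold higher, the chemokine gene CXCL5 at least 126-fold, TOP2A and the cytokinesis gene ANLN at least 114-fold, and the EGF receptor ligand EREG at least 84.8-fold. SERPINB2, an inhibitor of plasminogen activators, stood at 427 ± 137 CPM against a single count in hepatocyte, a ratio of 8971 (95% counting interval 1610 to 354335). The 10 of largest fold downward were CYP2A7, CYP2A6, FAM99A, CRP, CYP4A11, PLA2G2A, C3P1, INS-IGF2, CRYAA and UROC1. CRP fell from 23629 ± 6128 to 1.02 ± 0.925 CPM, and the fatty acid hydroxylase gene CYP4A11 from 981 ± 424 to 0.0716 ± 0.0101 CPM. CYP2A6 stood at 1336 ± 940 CPM in hepatocyte and at 3 counts in CdH, a ratio of 28544 (9766 to 138423), and shares reads with its paralog CYP2A7. The readthrough transcript INS-IGF2 overlaps IGF2, which fell 1356-fold from 2292 ± 106 to 1.69 ± 0.347 CPM.

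Mature liver functions fell together in CdH. All 14 secreted proteins were lower, with SERPINA1 15.7-fold lower and the fibrinogen gene FGA 51.1-fold lower. Of 22 enzymes and transporters, 20 were lower, among them CYP2E1 (92.6-fold), the urea cycle gene ASS1 (14.6-fold) and the gluconeogenic gene PCK1 (1782-fold). CYP1A2 was not, at 194 ± 108 CPM in CdH and 154 ± 91.0 CPM in hepatocyte. Adjusted over the list alone, 14 and 21 were lower. The camera test gave adjusted p = 9.67e-10 for each of these lists (adjusted p = 0.371 with an estimated correlation). Of 12 liver transcription factors, 9 were lower over all genes and 10 when adjusted over the list alone (adjusted p = 2.46e-05; adjusted p = 0.340 with an estimated correlation). FOXA3 fell 142-fold, NR1I3 72.1-fold, CEBPA 10.8-fold and NR1I2 3.65-fold. HNF4A was 2.58-fold lower but changed direction with library totals, to a log2 difference of 0.14, and 4 of the 12 stayed lower on that scale.

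Progenitor and biliary markers rose in CdH for 12 of 15 members over all genes, and 12 rose and 1 fell when adjusted over the list alone (camera, adjusted p = 5.79e-04; adjusted p = 0.371 with an estimated correlation). CD24 rose 182-fold, the hyaluronan receptor CD44 267-fold, the adhesion molecule EPCAM 64.8-fold, SOX9 41.3-fold and KRT8 3.64-fold. CD44 stood at 266 and 311 CPM in CdH and at 380 CPM in the library headed fibroblast, so it is not particular to progenitor cells. EPCAM was near the limit of detection in hepatocyte, at 3 and 4 counts. KRT18 stood at 2287 ± 517 CPM in CdH and 1367 ± 334 CPM in hepatocyte. All 16 proliferation genes rose, over all genes and when adjusted over the list alone (adjusted p = 8.34e-07; adjusted p = 0.371 with an estimated correlation). RRM2, a subunit of ribonucleotide reductase, rose 50.6-fold and PCNA, the replication clamp, 5.14-fold. The list's median log2 difference was 5.34, and 5.14 with genes at 0 counts set to their bound.

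Fetal liver markers moved both ways in CdH against hepatocyte. IGF2BP1, IGF2BP3 and PEG10 rose, and GPC3, H19, IGF2 and CYP3A7 fell, the same 3 and 4 of 12 when adjusted over the list alone (camera, adjusted p = 0.305). With library totals 4 rose and 3 fell, and the list's median turned from -0.42 to 0.40. IGF2BP1 was at 8 and 23 counts in CdH and at 0 in both hepatocyte libraries. GPC3 was at 2 and 0 counts in CdH and at 2 and 14 in hepatocyte. Both were near the limit of detection, so the sizes of their changes are uncertain. PEG10 stood at 718 and 35.0 CPM in the CdH libraries, so its rise of 183-fold joins unlike replicates. H19 fell 115-fold, AKR1C1 stood at 303 ± 169 and 492 ± 93.9 CPM, and CYP3A7 shares reads with CYP3A4. Of 3 measured pluripotency genes, TDGF1 fell, 2 fell when adjusted over the list alone (adjusted p = 0.481), and POU5F1 stood at 7.88 ± 1.25 and 3.42 ± 2.74 CPM. DPPA4 was at 0 counts in CdH and at 0.442 ± 0.504 CPM in hepatocyte. TDGF1 was near the limit of detection, at 3 and 1 counts in CdH and 31 and 4 in hepatocyte.

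On the TMM scale, genes responding to the signals targeted by the medium moved both ways in CdH against hepatocyte. With library totals, 9 TGF-beta, 11 Wnt and 13 growth factor response genes were higher, and 0, 1 and 0 lower. Of 12 TGF-beta response genes, 9 rose, among them THBS1 (10.4-fold) and TGFBI (4.86-fold), while 2 fell, SKIL among them, with the same counts adjusted over the list alone (camera, adjusted p = 0.110). ID1 stood at 121 ± 38.5 and 207 ± 54.6 CPM. Of 14 Wnt response genes, AXIN2, LGR5, RNF43, ZNRF3 and DKK1 rose and NOTUM fell; adjusted over the list alone, 6 rose and 3 fell (adjusted p = 0.0902). RNF43, a negative regulator of Wnt receptors, rose 28.0-fold and AXIN2 8.19-fold, while GLUL stood at 179 ± 20.4 and 323 ± 60.4 CPM and TBX3 at 42.1 ± 4.53 and 27.9 ± 14.2 CPM. Of 17 growth factor response genes, 9 rose, among them AREG (281-fold) and FOSL1 (59.4-fold), and DUSP6 and EGR1 fell, with the same counts adjusted over the list alone (adjusted p = 0.0902). CCND1 stood at 336 ± 30.0 and 186 ± 75.5 CPM, and IER3 at 111 ± 44.0 and 177 ± 93.1 CPM. AREG was near the limit of detection in hepatocyte, at 4 and 4 counts, so the size of its fold is uncertain. DUSP6 changed direction with library totals, to a log2 difference of 0.06.

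Stress and acute phase genes fell in CdH for 11 of 14 members over all genes and when adjusted over the list alone, and IL8 rose 26.0-fold (camera, adjusted p = 2.37e-05; adjusted p = 0.340 with an estimated correlation). SAA1, a serum amyloid, fell 96.7-fold, its near-identical neighbour SAA2 81.8-fold, the metallothionein MT2A 16.3-fold and JUN 22.7-fold. Of 19 fibroblast and mesenchymal markers, COL5A1, VIM, THY1 and ACTA2 rose and PDGFRB fell, also when adjusted over the list alone (adjusted p = 0.0635). With library totals 12 of the 19 were higher and 0 lower, and PDGFRB did not pass. VIM rose 115-fold, whereas COL1A1 stood at 13.0 ± 10.6 and 3.54 ± 0.651 CPM, COL1A2 at 4.70 ± 4.38 and 0.809 ± 0.661 CPM, and FN1 at 4141 ± 1627 and 1784 ± 587 CPM.

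Markers of other liver cells differed between the 2 hepatocyte libraries. C1QA stood at 1.37 CPM in hepatocyte 1 and 29.0 CPM in hepatocyte 2, and the median log2 CPM of the endothelial list was -2.42 and 0.76. Against that background, 7 of 13 macrophage and leukocyte markers fell in CdH and CD68 and LYZ rose, the same counts adjusted over the list alone (camera, adjusted p = 0.0635). CD14 fell 104-fold, from 1030 and 874 CPM in hepatocyte 1 and 2. It did not follow C1QA there, so its fall need not mean fewer macrophages. Without hepatocyte 2 the call of C1QA ended. Of 11 endothelial markers VWF, CDH5 and CLEC4G fell, and 0 did adjusted over the list alone or with library totals (adjusted p = 0.0896). CLEC4G turned to a log2 difference of 3.49 without hepatocyte 2. ALAS2 rose among 10 erythroid markers, and 0 did adjusted over the list alone (adjusted p = 0.764, with a median of -0.35, a mean of 0.18 and a median of 0.72 with library totals). Of 10 stellate cell markers 1 rose and COLEC11 fell, also when adjusted over the list alone, and 5 rose and 0 fell with library totals (adjusted p = 0.776, median 0.21, mean -0.46); RELN stood at 0.101 ± 0.00588 and 0.695 ± 0.822 CPM and CSPG4 at 1.28 ± 0.715 and 0.598 ± 0.123 CPM.

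**Figure D2:**
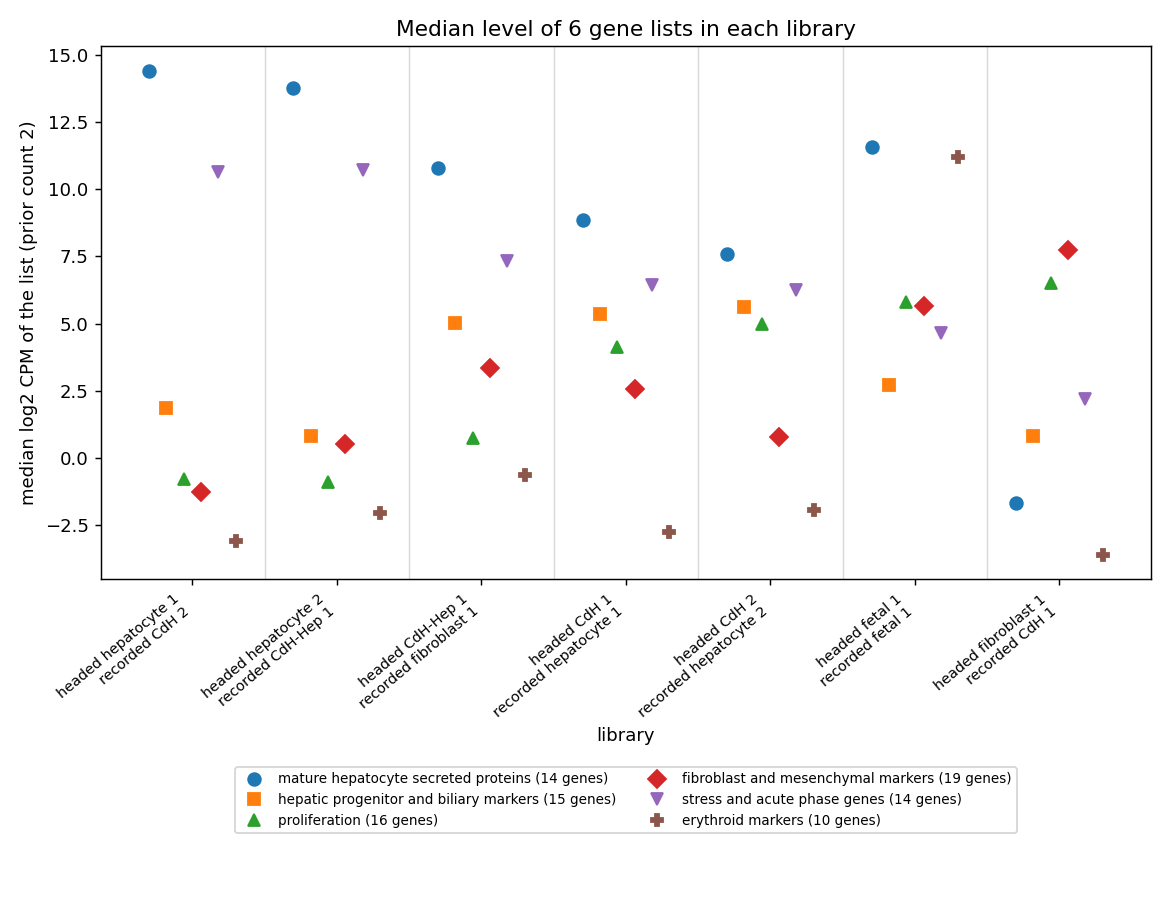
Median log2 CPM (vertical axis, prior count 2) of 6 gene lists (symbols) in each of the 7 libraries (horizontal axis, by header and record). The secreted proteins run from 14.42 in the library headed hepatocyte 1 to -1.68 in that headed fibroblast, and the fibroblast list is highest there, at 7.74.

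In CdH_Hep, 7 of 14 secreted liver proteins were higher than in CdH, and 13 of 16 proliferation genes and the biliary keratins KRT7 and KRT19 were lower. Among those 7, HP, SERPINA1, FGA, FGB and FGG are also acute phase proteins, so the 2 rises overlap. HP rose 157-fold, from 465 ± 504 to 73188 CPM, and SERPINA1, the protease inhibitor alpha-1 antitrypsin, 15.2-fold, to 92279 CPM. CRP rose 4721-fold, to 4775 CPM. KRT7 fell 38.2-fold, from 1425 ± 123 to 37.3 CPM, and MKI67 21.3-fold, to 3.25 CPM. ALB stood at 11212 CPM against 8756 ± 2359 CPM and did not pass, nor did TTR, at 27.3 against 42.0 ± 15.2 CPM, and APOA1, at 673 against 1124 ± 657 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 1244 genes, 698 higher and 546 lower, of which DESeq2 called 1232 among its 2225. CdH_Hep is 1 library, assumed to vary like the groups of 2, and with library totals the median gene moved from -0.04 to -0.84 and 13.7% of 2942 called genes were higher.

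The largest folds upward over CdH were those of REG1B, REG1A, SERPINB3, PLA2G2A, PLGLB2, CRP, C2CD4A, DMBT1, LTF and C2CD4B. REG1A, a secreted lectin known from injured pancreas and gut, stood at 461 CPM against 1 count in CdH, a ratio of 31882 (95% counting interval 5721 to 1259382). Its paralog REG1B was at least 1276-fold higher and SERPINB3, a squamous cell antigen, at least 586-fold. The secreted phospholipase gene PLA2G2A rose 7405-fold to 1030 CPM, and LTF, the iron-binding lactoferrin, 1347-fold to 159 CPM. In the CdH libraries PLA2G2A had 9 and 0 counts and LTF 0 and 8, so the sizes of these folds are uncertain. The largest downward were those of ANXA8, PTCD1, IGFL2, CPA4, SCEL, KRT81, PKMYT1, CEP55, BUB1B and SERPINB2. CPA4 fell 287-fold to 2.73 CPM, SERPINB2 60.9-fold, the hair keratin KRT81 84.5-fold and the spindle checkpoint kinase BUB1B 61.3-fold. PTCD1 was at 0 counts in CdH_Hep and at least 105-fold lower. The readthrough ATP5J2-PTCD1, which holds its sequence, stood at 18.9 CPM against 9.74 and 7.61 CPM. Reads may thus have been assigned to the readthrough, so the fall of PTCD1 need not be a fall in expression.

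Of 14 secreted proteins, 7 rose in CdH_Hep against CdH over all genes and 10 when adjusted over the list alone (camera, adjusted p = 1.60e-05; adjusted p = 0.513 with an estimated correlation). FGA rose 25.5-fold. Of 22 enzymes and transporters, 6 rose, and adjusted over the list alone 9 rose and 3 fell (adjusted p = 0.0167; adjusted p = 0.661 with an estimated correlation). CYP2E1 rose 29.7-fold, the arginase ARG1 64.9-fold, PCK1 66.0-fold and the asialoglycoprotein receptor ASGR1 22.2-fold. ASS1 stood at 381 CPM against 147 ± 9.69 CPM. FOXA3 and NR1I2 rose among 12 liver transcription factors, and 4 did adjusted over the list alone (adjusted p = 0.0128; adjusted p = 0.466 with an estimated correlation). The median of that list turned from 0.72 to -0.09 with library totals. HNF4A stood at 133 CPM against 72.5 ± 9.90 CPM, CEBPA at 64.6 against 13.1 ± 4.31 CPM and NR1I3 at 2.44 against 1.65 ± 0.136 CPM.

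KRT7, KRT19, EPCAM and CDH1 fell among 15 progenitor and biliary markers, also when adjusted over the list alone (camera, adjusted p = 0.0128; adjusted p = 0.513 with an estimated correlation). SOX9 stood at 32.4 CPM against 34.8 ± 8.68 CPM, KRT8 at 1848 against 4546 ± 798 CPM and KRT18 at 1499 against 2287 ± 517 CPM. Of 16 proliferation genes, 13 fell over all genes and 16 when adjusted over the list alone (adjusted p = 1.30e-08; adjusted p = 0.466 with an estimated correlation). TOP2A fell 22.0-fold and RRM2 36.8-fold, while PCNA stood at 26.6 CPM against 62.3 ± 5.64 CPM. Of 14 stress and acute phase genes, 7 rose and IL8 fell; adjusted over the list alone 9 rose and 3 fell (adjusted p = 0.00760; adjusted p = 0.466 with an estimated correlation). SAA1 rose 46.9-fold, SAA2 88.4-fold, MT2A 16.3-fold and the haem oxygenase HMOX1 8.42-fold. In the CdH libraries SAA1 stood at 1136 and 229 CPM and SAA2 at 383 and 59.9 CPM, so these 2 folds join unlike replicates.

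Growth factor response genes were lower in CdH_Hep for DUSP4, EREG and AREG and higher for SPRY4; of the 17, adjusted over the list alone, 2 rose and 7 fell (camera, adjusted p = 0.0295; adjusted p = 0.466 with an estimated correlation). With library totals 10 were lower and 0 higher, and SPRY4 did not pass; of the TGF-beta and the Wnt response genes 5 each were lower and 0 higher, and NOTUM did not pass. CTGF, THBS1 and INHBA fell among 12 TGF-beta response genes, where 1 rose and 3 fell adjusted over the list alone (adjusted p = 0.133). RNF43 and DKK1 fell and NOTUM rose among 14 Wnt response genes, also when adjusted over the list alone (adjusted p = 0.408). IGF2 rose 11.3-fold among 12 fetal liver markers, 2 rose and 1 fell adjusted over the list alone (adjusted p = 0.498), and AFP stood at 2.91 CPM. The fetal list's median was 0.12, and -0.02 with genes at 0 counts set to their bound and -0.46 with library totals. The 3 pluripotency genes did not pass on either adjustment (adjusted p = 0.760, median 0.00, mean 0.87).

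COL5A1, THY1, PDGFRB and FAP rose among 19 fibroblast and mesenchymal markers; adjusted over the list alone 8 rose and 2 fell (camera, adjusted p = 0.0128; adjusted p = 0.661 with an estimated correlation). With library totals 1 was higher, FAP, and 2 lower, and the median moved from 1.71 to 0.91. COL1A1 stood at 96.1 CPM and VIM at 87.3 CPM against 1074 ± 161 CPM. CD14 and CD74 rose among 13 macrophage and leukocyte markers, and 3 rose and 1 fell adjusted over the list alone (adjusted p = 0.117). That list's median turned from 0.76 to -0.05 with library totals. HBA2, HBG1, HBG2, SLC4A1 and EPB42 rose among 10 erythroid markers, and 7 did adjusted over the list alone (adjusted p = 6.36e-04; adjusted p = 0.466 with an estimated correlation), and 3 with library totals. Their levels were low, with HBG2 at 16.3 CPM, HBA2 at 12.9, HBA1 at 8.38 and HBG1 at 3.50 CPM, and each globin pair shares reads. None of 11 endothelial markers passed on either adjustment (edgeR; adjusted p = 0.845 by camera), with a median of -2.12, a bounded median of 1.25 and an upward test. None of 10 stellate cell markers did (adjusted p = 0.826), with a median of 0.44 that turned to -0.36 with library totals.

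Compared with hepatocyte, 15 of 22 enzymes and transporters were lower in CdH_Hep and 9 of 15 progenitor and biliary markers higher. CYP2B6 fell 938-fold, from 1448 ± 283 to 1.54 CPM, and TTR, the thyroxine carrier transthyretin, 406-fold, from 11111 ± 4526 to 27.3 CPM. CD44 rose 343-fold, to 371 CPM, CD24 115-fold and KRT19 66.0-fold, to 251 CPM. The library headed fibroblast held CD44 at 380, KRT19 at 302 and CD24 at 0.128 CPM. The levels of CD44 and KRT19 are thus not particular to progenitor or biliary cells. HP stood at 73188 CPM against 143173 ± 9689 CPM, and SERPINA1 at 92279 against 95138 ± 19895 CPM, and neither passed. ALB, at 11212 against 115962 ± 54101 CPM, did not pass either (edgeR, adjusted p = 0.0583). The edgeR quasi-likelihood test called 2778 genes, 1711 higher and 1067 lower, and DESeq2 3577, of which 2674 were shared and 1786 were higher. With library totals 85.8% of 4381 called genes were higher and the median gene moved from 0.09 to 0.75.

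The largest folds upward over hepatocyte were those of REG1A, REG1B, SERPINB3, HES2, ANKRD33, CXCL5, STC2, UNC5A, EPS8L3 and SPOCD1, all at 0 counts in both hepatocyte libraries. REG1A was at least 1544-fold higher, REG1B at least 375-fold, SERPINB3 at least 172-fold and STC2 at least 51.3-fold. The largest downward were those of INS-IGF2, CYP2A6, IL27, ESR1, PTCD1, CYP2A7, CYP4A11, LECT2, HSD17B13 and CYP2B7P1. For PTCD1, at 0 counts in CdH_Hep, the readthrough ATP5J2-PTCD1 stood at 18.9 CPM against 1.14 and 9.45 CPM in hepatocyte. Reads may have been assigned to that readthrough, so the fall of PTCD1 need not be a fall in expression. CYP2A6 fell from 1336 ± 940 to 0.214 CPM, CYP4A11 1895-fold, and HSD17B13, a lipid droplet protein, 1220-fold. ESR1, the estrogen receptor, was at 0 counts in CdH_Hep and at least 102-fold lower. The pseudogene CYP2B7P1 shares reads with CYP2B6.

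Of 14 secreted proteins, 8 were lower in CdH_Hep than in hepatocyte over all genes and 9 when adjusted over the list alone (camera, adjusted p = 7.20e-07; adjusted p = 0.429 with an estimated correlation). APOH fell 156-fold and APOA1 36.2-fold. Of 22 enzymes and transporters, 15 were lower, and 21 adjusted over the list alone (adjusted p = 1.28e-09; adjusted p = 0.429 with an estimated correlation). PCK1 fell 27.0-fold and CYP3A4 52.5-fold, while CYP2E1 stood at 1623 CPM against 5052 ± 193 CPM. FOXA3, PROX1 and NR1I3 fell among 12 liver transcription factors, and 4 did adjusted over the list alone (adjusted p = 0.00170; adjusted p = 0.429 with an estimated correlation). Of 14 stress and acute phase genes, FOS, JUN, ATF3, HSPA1A and HSPA1B fell; adjusted over the list alone 2 rose and 5 fell (adjusted p = 0.0169; adjusted p = 0.429 with an estimated correlation). HSPA1A and HSPA1B, near-identical heat shock genes, fell 17.5-fold and 12.9-fold, and FOS 23.4-fold.

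Progenitor and biliary markers rose for 9 of 15 members and CDH1 fell; adjusted over the list alone 10 rose and 1 fell (camera, adjusted p = 0.00138; adjusted p = 0.429 with an estimated correlation). SOX9 rose 38.4-fold and KRT7 7.64-fold. TOP2A, CCNB1, CDK1 and AURKA rose among 16 proliferation genes, and 11 did adjusted over the list alone (adjusted p = 0.00130; adjusted p = 0.491 with an estimated correlation). CCNB1 rose 21.4-fold to 6.37 CPM, and MKI67 stood at 3.25 against 0.285 ± 0.403 CPM. In the hepatocyte libraries CCNB1 was at 3 and 3 counts. TOP2A and CDK1 were at 0 in both, and at 36 and 15 counts in CdH_Hep. The sizes of these rises are therefore uncertain. Of 19 fibroblast and mesenchymal markers, 8 rose, and 9 did adjusted over the list alone (adjusted p = 0.00116; adjusted p = 0.491 with an estimated correlation). COL5A1 rose 323-fold, COL1A1 27.0-fold and VIM 9.36-fold. COL5A1 was at 1 and 8 counts in hepatocyte, so the size of its fold is uncertain. HBA2, HBG2 and SLC4A1 rose among 10 erythroid markers, and 5 did adjusted over the list alone (adjusted p = 0.00300; adjusted p = 0.429 with an estimated correlation).

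SMAD7, TGFBI, LTBP2 and TGFB1 rose and 2 genes fell, INHBA among them, of 12 TGF-beta response genes in CdH_Hep against hepatocyte; adjusted over the list alone 5 rose and 3 fell (camera, adjusted p = 0.680). TGFB1 rose 60.6-fold. LEF1, RNF43 and DKK1 rose among 14 Wnt response genes, also when adjusted over the list alone (adjusted p = 0.142). Of 17 growth factor response genes, 6 rose, AREG among them at 33.1-fold, and EGR1 and PHLDA1 fell; adjusted over the list alone 9 rose and 2 fell (adjusted p = 0.142). IGF2BP3 rose and IGF2 and CYP3A7 fell among 12 fetal liver markers, where 3 rose and 2 fell adjusted over the list alone (adjusted p = 0.381). The fetal list's median turned from -0.51 to 0.04 with library totals. CD68, LYZ and CD74 rose among 13 macrophage and leukocyte markers, and 3 rose and 6 fell adjusted over the list alone (adjusted p = 0.219). No pluripotency, endothelial or stellate cell marker passed on either adjustment (adjusted p = 0.645, 0.142 and 0.680 by camera; edgeR for the genes).

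**Figure D3:**
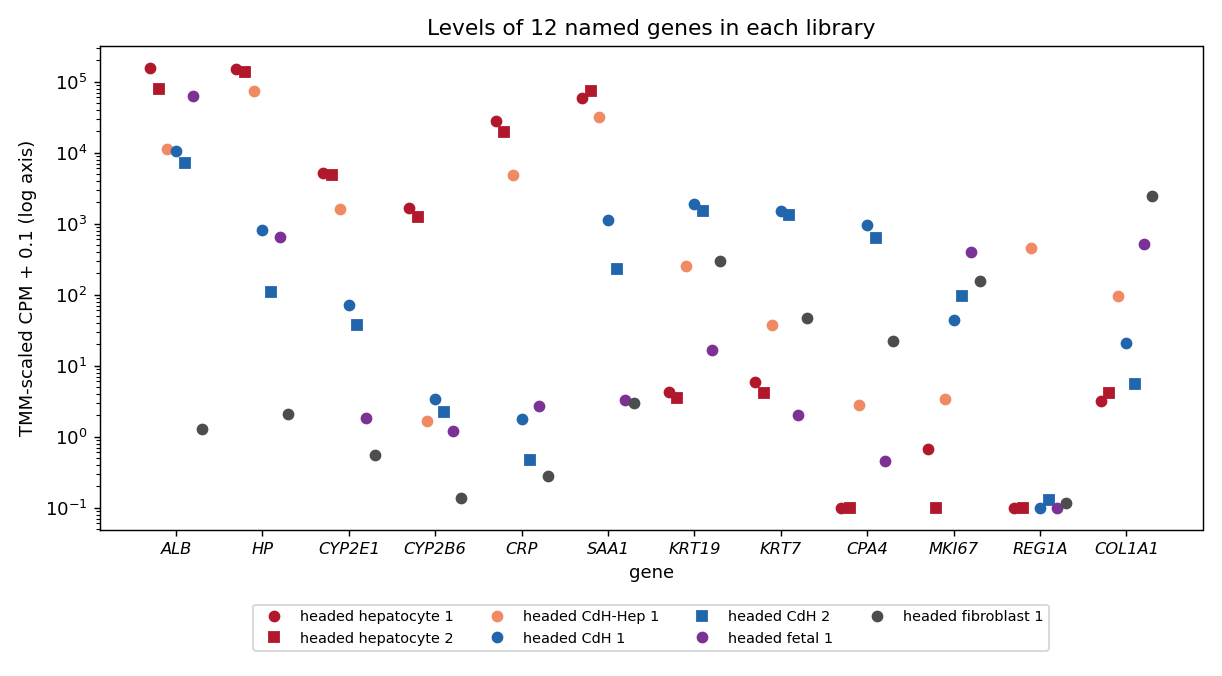
TMM-scaled CPM plus 0.1 (vertical log axis) of 12 genes (horizontal axis) in the 7 libraries, 1 point per library, colored by the group in its header and square for replicate 2. HP stands at 73188 in CdH_Hep, 821 and 109 in CdH, and 150024 and 136321 in hepatocyte, and REG1A at 461 in CdH_Hep.

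The fetal hepatocyte and fibroblast libraries were single and are described without a test, each list's median difference being placed among those of 10000 random lists of like expression. The fetal library held AFP at 4636 CPM, IGF2 at 13531 CPM and the imprinted RNA H19 at 21477 CPM. It held the fetal globin HBG2 at 79843 CPM, HBA2 at 74049, HBA1 at 39115 and HBG1 at 15065 CPM, and the sinusoidal endothelial receptor STAB2 at 141 CPM, CLDN5 at 46.5, CDH5 at 36.3 and LYVE1 at 23.4 CPM. Relative to hepatocyte, its fetal liver markers had a median log2 difference of 4.89, proliferation 6.31 and erythroid markers 14.53, each near the top of the random lists. Secreted proteins stood at -2.62 and enzymes and transporters at -3.90, at percentile 0.0.

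CdH stood below the fetal library in fetal liver markers, with a median log2 difference of -7.91 at percentile 0.0, and above it in progenitor and biliary markers, with 4.35, near the top of the random lists. Proliferation stood at -1.26, at percentile 0.4. CdH_Hep stood at -6.88 for fetal liver markers (percentile 0.0), at 3.38 for progenitor and biliary markers (near the top) and at -1.83 for secreted proteins (percentile 0.0). Enzymes and transporters of CdH_Hep stood at -0.04 from the fetal library, at percentile 17.0. Against the fibroblast library, CdH had a median of -7.76 for fibroblast and mesenchymal markers (percentile 0.0), of 9.75 for secreted proteins and of 5.97 for liver transcription factors (both near the top). The fibroblast library held COL1A2 at 3806 CPM, VIM at 4470 CPM and the surface marker THY1 at 753 CPM, against 2.26 and 1.92 CPM of THY1 in CdH.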

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

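Library totals in place of TMM, and for the header assignment the RLE factors, the fits of only the libraries compared and limma on TPM, were chosen after seeing the data. By the header, 2314 of 2323 alternatives of 225 gene results kept their direction, and 2158 kept direction and side of the threshold. These genes were named from the same data, many for their large folds, so this agreement says little about other genes. Over all genes, library totals shared 4881 of the 6702 calls in CdH against hepatocyte. They shared 948 of 1244 in CdH_Hep against CdH and 2331 of 2778 in CdH_Hep against hepatocyte. By the record the counts of 0 became, for CdH against hepatocyte, 519 with DESeq2, 0 to 6596 leaving out 1 replicate and 6702 by the header. For CdH_Hep against CdH they became 141 with DESeq2, 0 to 8700 leaving out 1 replicate (6 without CdH replicate 1, 8700 without CdH replicate 2) and 1244 by the header. For CdH_Hep against hepatocyte they became 458 with DESeq2, 7245 with only the libraries compared, 0 to 7156 leaving out 1 replicate and 2778 by the header. With CdH replicate 2 left out the counts for the first and last contrast were 5935 and 6997, and with CdH replicate 1 left out 6596 and 7156. Where a library recorded as CdH was left out, or that group was not in the fit, only the pair recorded as hepatocyte set the spread. That pair correlated at 0.98, against 0.54 for the pair recorded as CdH. Apart from this and the assignment, which changes which libraries form a group, the cause was not tested.

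By the header, CdH against hepatocyte called 10877 genes with library totals and 11741 with limma. CdH_Hep against CdH called 2225 with DESeq2, 2096 with no filter, 2942 with library totals, 3313 with only the libraries compared, 7062 with limma and 888 to 2916 leaving out 1 replicate (1276 without CdH replicate 1, 888 without CdH replicate 2, 2897 without hepatocyte replicate 1, 2916 without hepatocyte replicate 2). CdH_Hep against hepatocyte called 4381 with library totals. The cause was not tested. Of the gene lists in CdH against hepatocyte, 1 passed by the record, 0 with an estimated correlation, 6 by the header and 0 by the header with an estimated correlation. The correlation of the recorded CdH pair, 0.54, was 0.98 for the pair headed CdH. A replicate block called 0 genes by the record and 6788 by the header. The deviations of same-numbered replicates correlated at -0.06 and 0.09 (Spearman -0.06 and 0.13). These low values gave little sign that the numbers pair samples, but 2 groups of 2 cannot settle it.

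Assigned by header instead of record, the log2 differences of CdH against hepatocyte turned to -2.04 for PCDH18, -11.08 for A1BG, -3.12 for ADAM33, -3.92 for FLT1, -3.96 for ENPP2, -2.06 for LY6K, -10.41 for IGF2, -0.67 for FAM65B, -2.59 for SLC8A1, -10.18 for CD4 and -3.73 for ALB. They turned to 7.02 for SLC6A19, 7.81 for SCEL, 4.52 for ANXA8L2, 11.92 for EPS8L3, 11.54 for ANXA8, 11.46 for TMEM233, 13.72 for HES2, 10.62 for ANKRD1, 5.57 for EHF, 9.68 for CTSE, 1.09 for AFP, 8.80 for KRT19, 5.37 for SOX9 and 6.02 for EPCAM. Within the record, ALB turned from 3.14 to -4.89 and -5.20 with limma at pseudocounts 1 and 0.1, to -3.23 with the replicate block, and ranged from -12.82 to 4.15 leaving out 1 replicate. MKI67 turned from 0.18 to -1.36 and -2.75 with limma and -2.51 with the block, and ranged from -6.90 to 1.17. COL1A1 ranged from -2.06 to 7.82. By the header, HNF4A turned to 0.14 with library totals and 0.59 with limma, DUSP6 to 0.06 and 0.40, and ALB in CdH_Hep against CdH to -0.45 and -0.75. CYP1A2 ranged from -0.38 to 1.12 and CLEC4G from -9.73 to 3.49 leaving out 1 replicate. The cause was not tested. Depth set the lower limit of 3 counts, 0.081 to 0.178 CPM of a library's total and 0.0547 to 0.342 CPM on the TMM scale.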

Other observations

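Assigned by header, 5 gene lists that were added after the levels had been seen describe CdH_Hep further. Because they were picked from the same levels, camera tests of them are no independent support: all 5 passed against CdH with the preset correlation, and none did with an estimated correlation (adjusted p = 0.205 for each). Of 11 metallothioneins, 10 were higher than in CdH over all genes and when adjusted over the list alone, and 10 with library totals. MT1G stood at 2620 CPM in CdH_Hep, 32.9 and 11.8 CPM in CdH, and 1105 and 300 CPM in hepatocyte. Of 22 complement proteins, 15 were higher, and 18 adjusted over the list alone. C1R stood at 1336 CPM against 13.8 and 11.1 CPM in CdH, and CFB at 4569 CPM against 70.2 and 32.7 CPM. Of 9 class II antigen presentation genes, 5 were higher, and 8 adjusted over the list alone. HLA-DRA stood at 75.4 CPM, above 0.516 and 0.420 CPM in CdH and above 2.97 and 21.7 CPM in hepatocyte. All 11 acute phase proteins were higher, over all genes, when adjusted over the list alone and with library totals. HP, SERPINA1, FGA, FGB and FGG among them are counted with the secreted proteins too, and CRP, SAA1 and SAA2 with the stress genes.

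Of 10 measured neutrophil markers, 2 were higher in CdH_Hep than in CdH, and 5 adjusted over the list alone. In CdH itself the xenobiotic-inducible CYP1A1 stood at 486 and 444 CPM, against 2.28 and 5.96 CPM in hepatocyte and 50.5 CPM in CdH_Hep, and UGT1A1, which conjugates bilirubin, at 1371 and 1070 CPM against 67.2 and 23.1 CPM. UGT1A6 of the same family stood the other way, at 338 and 386 CPM in CdH against 753 and 584 CPM in hepatocyte. Reads that the 2 genes share are split by estimate, so the size of the UGT1A1 difference is uncertain. S100A6 stood at 1937 and 1897 CPM against 1.48 and 4.09 CPM. These genes were chosen after their values were seen.

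For the disagreement between records and headers, both tests were fixed before the values were seen. The 2 libraries headed hepatocyte correlated at 0.96 and the 2 recorded as CdH at 0.54. Secreted liver proteins had medians of 14.42 and 13.77 (log2 CPM) in the libraries headed hepatocyte. Their medians were 8.84 and 7.59 in the libraries recorded as hepatocyte, and -1.68 in that recorded as CdH 1. These values argue against the record for these files, and for sample records attached to the wrong files. The fibroblast list had its highest median, 7.74, in the library headed fibroblast and 3.33 in that recorded as fibroblast, which is likewise consistent with a wrong record for that file. Unlike cultures of true CdH replicates could not give the library recorded as fibroblast its SERPINA1 at 92279 CPM and HNF4A at 133 CPM.

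For the erythroid transcripts in the library headed CdH_Hep, both tests were chosen only after the result was seen. Reads carried over from the fetal hepatocyte library could explain them: 10 other genes high in the fetal library, pooled, stood in CdH_Hep at 253 ppm of their fetal level (95% interval 138 to 425, 14 counts, with FAM178B, HBE1, HBM and TSPAN32 at 0), against 200 ppm (188 to 212) for the erythroid markers. Most of those 10 genes, such as GATA1, GFI1B and HBZ, are erythroid themselves, so carried reads and RNA of fetal-type red cells are not told apart. Blood cells with adult haemoglobin are unlikely, since HBB amounted to 1.29% of HBG1 and HBG2 together. Expression of fetal globins by the cells themselves was not tested.

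For the acute phase proteins in the library headed CdH_Hep, all 3 tests were chosen only after the result was seen. Admixed hepatocyte RNA is unlikely to account for them, because 20 of 36 hepatocyte genes stood below 2.02% of their hepatocyte level, where CRP stood at 20.2%. Leukocyte RNA is unlikely to account for them, as PTPRC, carried by all leukocytes, was at 0 counts and the highest of 6 measured leukocyte genes, FCGR3B, stood at 0.641 CPM. CD74 at 501, S100A8 at 8.85 and S100A9 at 442 CPM were above their levels in CdH, and a small leukocyte share stays open. CD14, at 314 CPM, cannot decide this. The hepatocyte libraries held CD14 at 1030 and 874 CPM, with PTPRC at 0 and 0.681 CPM. Scaling does not account for the rise, since the smallest log2 difference with library totals was 3.12, for SERPINA1, and differentiation of CdH toward hepatocytes stays an untested hypothesis from 1 library. Other causes of a rise in acute phase proteins were not tested.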
